A study of Mus musculus with 3 samples.

How the data were processed

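The series holds 3 single-cell ATAC-seq libraries of pooled nuclei from whole, unsorted lungs of black 6 mice, 1 library per day: day 0 without injury, and days 14 and 35 after bleomycin. The number of animals in each pool is not given in the sources used here. For each library the deposited files hold a matrix of counts per peak and barcode, a matrix of counts per transcription factor motif and barcode, and the positions of the peaks on mm10. The matrix of counts per peak was made with Cell Ranger ATAC 2.1.0 per the file headers, and the origin of the motif matrix was not checked. Cell Ranger and Signac are also named in the submitters' processing notes, with no role given, and the aligner, the settings for peaks and the calling of cells are not stated. The deposited counts are whole numbers without normalization. Even values outnumber odd ones, as 2 cut sites per fragment give, so intervals of accessibility were taken on halved counts. Intervals for shares of barcodes and of peaks used their numbers as they are. A motif's deposited counts are summed over the peaks assigned to it, and its peaks were recovered by matching counts, which succeeded for 362, 405 and 319 motifs on days 0, 14 and 35, with medians of 18, 18 and 19 peaks.

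Peaks were called in each library on its own list. Overlaps between peak lists were taken with bedtools 2.31.1 (minimum overlap 1 bp). Overlapping peaks were merged into 68405 regions, and only the 32979 that held a peak of all 3 libraries were compared, since a region without a peak has no count in that library. Of the rest, 6956, 4782 and 9206 were of day 0, day 14 and day 35 alone, and 1438, 8981 and 4063 of days 0 and 14, 0 and 35, and 14 and 35. Gene positions came from a table of the same assembly without strand, so genes took regions in their body and 2 kb on both sides, and the alternative for promoters took 1 kb around both gene ends. Of the genes in the marker and gene lists, 231 of 411 had a shared region. Values are CPM, counts scaled to the same total in shared regions for each library or class.

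Ratios between days carry exact conditional binomial 95% intervals, single values exact Poisson intervals and shares exact binomial intervals. Genes needed 200 counts and regions 100 counts over both libraries. With 1 library per day no statistical test was made, and these intervals leave out the spread between animals and between preparations. Each of the fixed gene lists, marker lists and motif lists was summarized by its median log2 ratio if at least 3 genes or 2 motifs were measured. The median was placed among those of 10000 random lists of the same size. Members of the random lists were matched for accessibility for gene and marker lists, but not for motif lists. Marker lists of other macrophages and monocytes, neutrophils, NK cells, mesothelial cells, mast cells, erythroid cells, megakaryocytes and Schwann cells had fewer than 3 measured genes and no value.

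Barcodes were clustered jointly on presence of counts in shared regions: TF-IDF, 50 components by truncated SVD, of which component 1 was left out for its correlation with depth (Spearman 0.994 in size), 15 nearest neighbours, and Leiden clustering at resolution 1. Clusters were named from fixed markers in each library's own peaks. The naming thresholds, a score of 0.5 and a lead of 0.2 over the next type, were set after the data were seen. Classes with at least 200 barcodes in every library were compared. A score from simulated doublets had medians of 0.733, 0.700 and 0.700 in barcodes and 0.800, 0.733 and 0.800 in simulated doublets, so it separated them poorly and no barcode was removed as a doublet.

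Named genes follow a rule of size. In all cells and in the fibroblast-like class these are the 6 highest and 6 lowest ratios of at least 1.5-fold whose interval leaves out 1, without predicted genes, and in other classes the first 3 each way, of which the text gives a part. The rule further covers up to 4 members of each list that lay at 1.5-fold or farthest from its median, the 4 study genes, 8 motifs and 3 regions each way. The groups, comparisons, lists, this rule and the first set of alternatives were fixed before the data were examined. Chosen after the data were seen were the aligned regions (30534 of the shared regions, where the part common to the 3 peaks is at least 0.8 of the region), the rule applied in them (up to 12 each way in all cells and the fibroblast-like class and 6 in others), barcodes with at least 6000 counts, components weighted by singular value, motif counts in regions tied to the motif on all days, and the omission of high doublet scores for genes and lists.

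Other alternatives were peak overlap of 50% both ways, equal numbers of peaks, other scales and minimums, equal weight per barcode, regions of matched width (31770), class shares held at day 0, resolutions 0.5 and 2, thinning to 1000 counts, and each library clustered on its own. Minimums of 1000 and 3000 counts removed no barcode, as the smallest held 3022. The pipeline was tested on simulated data with the depth of these libraries, and simulated 2-fold genes passed 1.5-fold in 100% of cases. Simulated 1.5-fold genes passed in 37.5%, 40.0% and 27.5% over the comparisons when higher, and in 60.0%, 65.0% and 50.0% when lower. Unchanged genes passed in 0.0%, and 5 of 5 simulated classes were recovered. Simulated intervals of unchanged genes held the true value in 95.3%, 95.5% and 95.0%. The simulated counts had counting error alone, and the simulated classes had no mixed barcodes, doublets or differences between libraries. Recovery in them thus does not show that the clusters or ratios of the real barcodes are right. All tests of explanations in the closing section were written after the results were seen. For the genes with the same direction in every class, the tests on counts of other cells and on class mix were also revised after their first values were seen, and for the class mix 2 decision rules were tried before the earlier one was restored, which leaves that explanation open. The tests on peak width for genes without an aligned region and on barcodes with few counts were likewise set to open after their values were seen.

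Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, python-igraph 0.11.9, numba 0.67.0 and matplotlib 3.10.9.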

Results

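Chromatin accessibility was measured by single-cell ATAC-seq in nuclei from unsorted lung cells of black 6 mice, without injury (day 0) and at day 14 and day 35 after bleomycin, a drug whose instillation causes lung injury and scarring. ATAC-seq uses a transposase that cuts open DNA, and each cut site inside a peak adds to the count of that peak. The comparisons ask how the open chromatin of the lung differed from the uninjured state at the earlier and at the later day, and between both days. Each day was 1 library made from pooled nuclei, so there were no replicates, no test was made between days, and every interval given covers counting error only. The libraries held 20018, 18464 and 20008 barcodes on days 0, 14 and 35, with 121308266, 84130618 and 157571512 counts in peaks and medians of 5591, 4206 and 7192.5 counts per barcode. Day 14 was thus the shallowest library and had the shortest peak list, with 43381 peaks against 50526 on day 0 and 55318 on day 35. The peaks covered 42.5, 36.7 and 46.8 Mb with mean widths of 842, 845 and 846 bp. Values are compared in 32979 regions that held a peak of every library, which took 83.1%, 89.2% and 79.1% of the counts, and are given as CPM, the counts scaled to the same total in those regions. Genes took the regions in their body and within 2 kb on both sides, which gave 13615 of 21900 protein-coding genes a value.

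At day 14 T cell markers had the highest median against day 0 of all gene and marker lists with a value, and endothelial markers the lowest. Ctss, which encodes the lysosomal protease cathepsin S of antigen-presenting cells, had 16.6 CPM against 6.51 (ratio 2.55, 2.22 to 2.92), and Ccl2, the chemokine that draws monocytes, had 15.9 against 6.40 (ratio 2.49, 2.18 to 2.87). Itgb2, the shared chain of leukocyte integrins, had 63.5 against 26.2 CPM (ratio 2.43, 2.27 to 2.60). Sftpc, the surfactant protein gene of alveolar type 2 (AT2) cells, had 64.5 against 106 CPM (ratio 0.610, 0.581 to 0.640), and Nr4a1, an early-response nuclear receptor, had 119 against 232 (ratio 0.512, 0.495 to 0.530). Of all genes, 4.44% lay at least 1.5-fold apart, and the median log2 ratio was 0.02.

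The genes farthest above day 0 at day 14 by the fixed rule were Ptafr (ratio 3.11), Cd300lf (2.96, 2.59 to 3.40), Fgd3 (2.78), Tmc1 (2.66), Slfn8 (2.64) and Treml2 (2.59). Those farthest below were Prdm8 (0.386), Nova2 (0.443), Hsp90ab1 (0.444, but 0.906 in regions of matched width), Spry1 (0.445), Kansl1l (0.456) and Sec14l4 (0.470). Ptafr, Fgd3, Treml2, Prdm8, Hsp90ab1, Spry1 and Kansl1l rested on regions where the libraries' peaks differed in extent, and had no region in which the part common to the 3 libraries reached 0.8 of the region, called aligned below. The rule in aligned regions, chosen after the values were seen and taken to 12 genes each way instead of 6, also led to Gpa33 (2.60), Nckap1l (2.57), Cd84 (2.55), Aim2 (2.35), Ncf4 (2.33) and Csf2rb (2.28) on the higher side. On the lower side it led to Aff3 (0.481), Klf15 (0.512), Slc38a4 (0.532), Zbtb16 (0.533) and Nsg1 (0.548). Nckap1l, Ncf4 and Csf2rb act in blood cells, as part of actin remodelling, of the phagocyte oxidase and of cytokine reception.

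**Figure D1:**
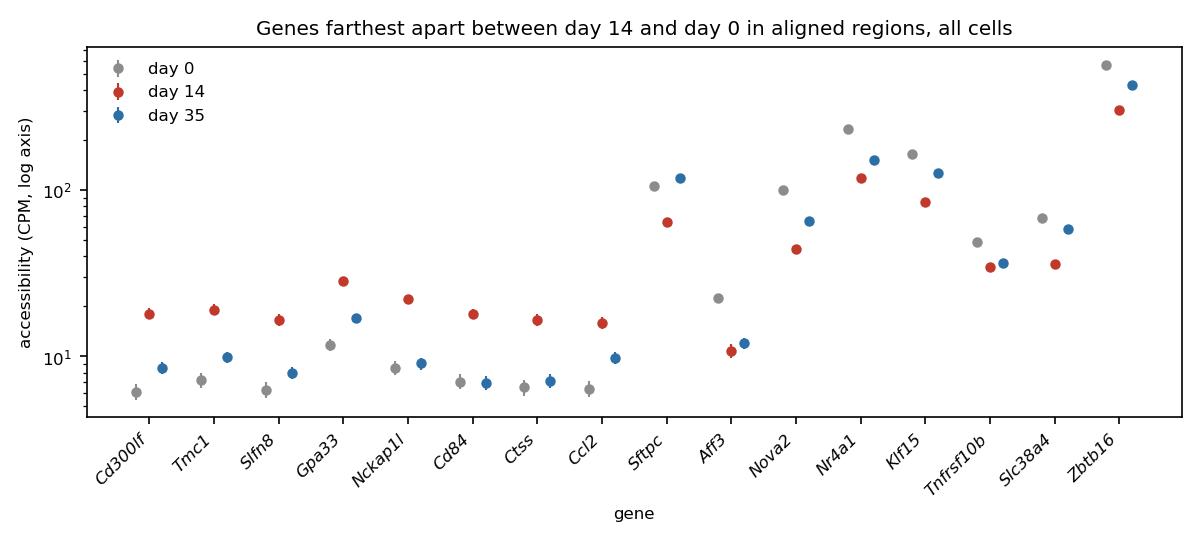
Accessibility in CPM (log axis) of the 16 genes farthest apart between day 14 and day 0 in aligned regions, for all cells of the 1 library per day; points are the values and bars their 95% counting intervals. The genes were chosen by their ratio in aligned regions, while the values shown are over all their shared regions. Cd300lf stood at 6.11 CPM on day 0, 18.1 on day 14 and 8.57 on day 35.

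Marker lists of lymphocytes were the highest of the cell type lists with a value at day 14. Lists of other macrophages and monocytes and of neutrophils could not be ranked, as too few of their genes had a shared region. Of their genes, C1qa, C1qb, C1qc, Csf1r, Ms4a7, Cx3cr1, Ly6c2, S100a8, Mmp8 and Cxcr2 had a peak at day 14 but not on day 0, and Plac8 the reverse. The T cell markers had a median log2 ratio of 0.68 with 4 of 5 genes above 0 (percentile 99.4 among random lists of matched accessibility), including Cd3d, a chain of the T cell receptor complex, at 31.2 against 16.2 CPM (ratio 1.93). The B cell markers had 0.51 with 9 of 9 above 0 (percentile 98.8), with Bank1 at a ratio of 1.62 and Fcrla at 1.54. Dendritic cell markers had 0.31 (percentile 97.1), the list of regulatory and exhausted T cells 0.36 with 3 of 3 above 0 (percentile 85.7), alveolar macrophage markers 0.06 and plasma cell markers 0.02. The lists of endothelial markers (−0.48, 0 of 8 above 0, percentile 0), endothelial capillary genes (−0.26, 0 of 4) and lymphatic endothelial markers (−0.24) were lower. These 3 medians were −0.10, −0.0101 and 0.0539 when class shares were held at day 0. Cdh5, the cadherin of endothelial junctions, had 23.6 against 38.2 CPM (ratio 0.617, 0.569 to 0.668), and Cd93 a ratio of 0.574. The venous and systemic endothelial list stood at 0.26 with 5 of 7 above 0, and at 0.04 in aligned regions, where Selp has no region.

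Most epithelial lists had medians below 0 at day 14, though those of surfactant, AT2 and transitional epithelium genes were no lower than that of housekeeping genes (−0.17). The medians were −0.28 for club and secretory markers (0 of 6 above 0), −0.23 for alveolar type 1 (AT1) markers (3 of 10), −0.17 for the surfactant list (2 of 10; 0.00295 in barcodes with at least 6000 counts and −0.0526 with class shares held at day 0), −0.13 for AT2 markers, −0.13 for the transitional epithelium list (5 of 12) and 0.05 for ciliated markers. Sftpa1 had 21.1 against 36.8 CPM (ratio 0.573, 0.527 to 0.623), Sftpb 54.7 against 79.2 (ratio 0.691) and Krt18 17.3 against 24.0 (ratio 0.718). Pdpn, a surface glycoprotein of AT1 cells that other cells of injured tissue also make, went the other way, with 19.0 against 8.45 CPM (ratio 2.25, 1.99 to 2.54). Lgals3, of the transitional list and the injury macrophage list, had a ratio of 1.58.

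Matrix, fibroblast and signalling lists had medians from −0.25 to 0.15. The collagen and matrix list had a median of 0.14 with 9 of 11 genes above 0 (percentile 57.6). That median leaves out Eln, Col1a2, Lox and Col6a1, which had a peak on day 0 but not at day 14, and Col5a2, with the reverse. Of the measured members, Fn1 (fibronectin, 25.6 against 16.4 CPM, ratio 1.56, 1.42 to 1.72) and Vcan (ratio 1.48, 1.33 to 1.66) stood high, while Col1a1 was at 30.8 against 30.2. Among proteases and inhibitors (median 0.11, percentile 65.2), Mmp2 had a ratio of 1.76 (1.53 to 2.02) and Plau of 1.72 (1.58 to 1.89). The medians were 0.09 for the TGF-beta pathway (11 of 16 above 0, percentile 95.9), 0.05 for the Wnt pathway, 0.15 for adventitial fibroblast genes, 0.02 for contractile genes, −0.13 for alveolar fibroblast genes, −0.25 for fibroblast markers and 0.02 for smooth muscle and pericyte markers. Inflammatory cytokines had a median of 0.02 with 5 of 9 above 0, of which Ccl2 (2.49), Cxcl2 (2.09), Il6 (27.9 against 13.8 CPM, ratio 2.03, 1.84 to 2.23) and Il1a (1.54) had the highest ratios. That median leaves out Il1b, Tnf, Ccl3, Ccl4, Osm and Il1rn, which had a peak at day 14 but not on day 0. It also leaves out Cxcl5 and Cxcl12, which had a peak on day 0 but not at day 14. The interferon list had 0.09 with 9 of 12 above 0, led by Gbp2 (1.53) and Ifit3 (1.48), and the injury macrophage list 0.06. The latter has no value for Spp1 and Trem2, with a peak at day 14 but not on day 0, nor for Apoe, with the reverse.

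Genes of the cell cycle were higher at day 14, with a median log2 ratio of 0.24, 10 of 12 above 0 and percentile 99.8. Mki67, a marker of dividing cells, had 45.2 against 29.8 CPM (ratio 1.52, 1.41 to 1.63) and Aurkb a ratio of 1.29. The p53 and senescence list was lower (−0.20, 3 of 11 above 0, percentile 0.590), with Plk2 at 0.669 and Cdkn1a, which halts the cell cycle, at 143 against 182 CPM (ratio 0.785), although Ccng1 stood at 1.29. Housekeeping genes had a median of −0.17 with 3 of 10 above 0, so that a gene at that level was no lower than this list.

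Day 35 lay closer to day 0 than day 14 did, and the lowest list medians were those of lymphatic and other endothelial markers. Only 1.45% of genes were at least 1.5-fold apart from day 0, with a median log2 ratio of −0.02. Lyve1, a hyaluronan receptor of lymphatic endothelium, had 15.4 against 31.7 CPM (ratio 0.486, 0.448 to 0.527), and Gimap6 had 27.2 against 53.6 (ratio 0.507, 0.476 to 0.538). On the higher side stood Gata4, a transcription factor, with 17.9 against 8.70 CPM (ratio 2.06, 1.85 to 2.31), Fetub with 29.5 against 14.6 (ratio 2.02, 1.85 to 2.20) and Il6 with 24.8 against 13.8 (ratio 1.80, 1.65 to 1.97).

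The fixed rule also named Zfp423 (ratio 3.37), Ptafr (2.38), Plxnb1 (2.09) and Nek5 (2.01) above day 0, and Kcnab1 (0.495), Kansl1l (0.503) and Ctla2a with Tpbpa, which share their regions (0.513), below. Zfp423, Ptafr, Plxnb1, Nek5 and Kansl1l had no aligned region. In aligned regions the rule went on to Fcer2a, Ahnak2 (1.91), Gja1 (1.80), Rspo2 (1.80), Wnt7a (1.79) and Bdnf (1.78) above, and to Tnfrsf10b (0.427, but 0.748 over all its regions), Aff3 (0.536), Itga2 (0.540), Ctla2b (0.551) and Cdh5 (0.560) below. Wnt7a and Rspo2 encode secreted activators of Wnt signalling.

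Epithelial lists were above day 0 at day 35. The transitional epithelium list had a median of 0.27 with 11 of 12 genes above 0, the surfactant list 0.21 with 10 of 10, AT1 markers 0.26 with 9 of 10 and AT2 markers 0.24 with 11 of 11, each at percentile 100. Holding class shares at day 0 gave 0.14, 0.0726, 0.0799 and 0.0748. Areg, a growth factor for the EGF receptor, had 30.4 against 19.7 CPM (ratio 1.55, 1.43 to 1.67), Krt7 a ratio of 1.36 and Itgb6, a chain of the integrin that activates TGF-beta, a ratio of 1.39. Ciliated markers had 0.16 and club and secretory markers 0.10. Endothelial markers remained below day 0 (−0.50, 0 of 8 above 0), as did lymphatic markers (−0.58) and the capillary list (−0.37, 0 of 4). B cell markers, above day 0 at day 14, were below it (−0.29), and among them Ms4a1 had a ratio of 0.693. The medians of these 4 lists with shares held were −0.0544, −0.25, −0.13 and −0.13. T cell markers had 0.25 (percentile 96.4), although their member Cd3d stood lower, at 12.4 CPM against 16.2 on day 0. The share of barcodes in the T-like class, described below, was also lower at day 35, with 2.61% against 4.90%. Dendritic (0.06), alveolar macrophage (−0.03) and plasma cell markers (−0.05) were near 0.

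Inflammatory cytokines were the highest of the signalling lists at day 35 (0.30, 6 of 9 above 0, percentile 99.9), with Cxcl2 at a ratio of 1.87 and Cxcl1 at 1.44, both chemokines for neutrophils. The contractile list had 0.19 (5 of 6, percentile 98.5), the TGF-beta pathway 0.12 (11 of 16, percentile 99.8), the interferon list 0.11 (8 of 12, percentile 98.2), the Wnt pathway 0.12 and collagen and matrix 0.09 (7 of 11, percentile 87.6). The collagen and matrix median leaves out Col1a2, Lox and Cthrc1, which had a peak on day 0 but not at day 35. The TGF-beta median was −0.00 when only gene ends were counted. Adventitial fibroblast genes had 0.14, alveolar fibroblast genes and fibroblast markers 0.03, smooth muscle and pericyte markers 0.14, proteases 0.06, the venous list 0.08, regulatory T cells 0.03 and injury macrophages −0.02. Pdgfa, a growth factor for mesenchymal cells, had a ratio of 1.52 (1.46 to 1.59). The cell cycle list was at −0.04 with 4 of 12 above 0, p53 and senescence at −0.14 and housekeeping genes at −0.17 (1 of 10).

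Between both injured days, B and T cell markers were lower and surfactant genes higher at day 35. Sftpa1 had 43.5 against 21.1 CPM (ratio 2.06, 1.91 to 2.24), Sftpb 94.6 against 54.7 (ratio 1.73) and Sox2, a transcription factor of the airway epithelium, 33.2 against 19.2 (ratio 1.73). Cd3d had 12.4 against 31.2 CPM (ratio 0.396, 0.361 to 0.434), Cd84 6.96 against 18.0 (ratio 0.386), Ms4a6d 5.21 against 14.9 (ratio 0.350), Dock10 10.6 against 29.8 (ratio 0.355), Stap1 5.64 against 14.9 (ratio 0.378) and Dthd1 5.97 against 15.7 (ratio 0.381). At least 1.5-fold differences held for 4.03% of genes. The remaining genes of the rule, Zfp423, Plxnb1, Spry1, Prdm8 and Il17d above (2.56 to 2.06) and Treml2 below (0.226), had no aligned region.

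The list medians at day 35 against day 14 were highest for AT1 markers (0.47), surfactant (0.46, 10 of 10 above 0), club and secretory markers (0.44), AT2 markers (0.37) and transitional epithelium (0.32), and lowest for B cell (−0.74), T cell (−0.43), lymphatic (−0.40) and dendritic markers (−0.27). AT1 markers, surfactant and AT2 markers had 0.27, 0.17 and 0.20 with class shares held at day 0. Cell cycle genes were lower (−0.18, 0 of 12 above 0, percentile 1.22), and p53 and senescence genes higher (0.11). Fibroblast lists stood at 0.16 for alveolar, adventitial (−0.0541 with shares held) and marker genes alike, contractile genes at 0.03, collagen and matrix at −0.10, smooth muscle and pericyte markers at 0.18 and ciliated markers at 0.13. The others were Wnt pathway 0.12, TGF-beta pathway 0.02, inflammatory cytokines 0.02, housekeeping 0.02, endothelial markers −0.03, proteases −0.04, alveolar macrophages −0.04, interferon −0.05, injury macrophages −0.06, plasma cells −0.07, venous genes −0.10, capillary genes −0.11 and regulatory T cells −0.15.

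**Figure D2:**
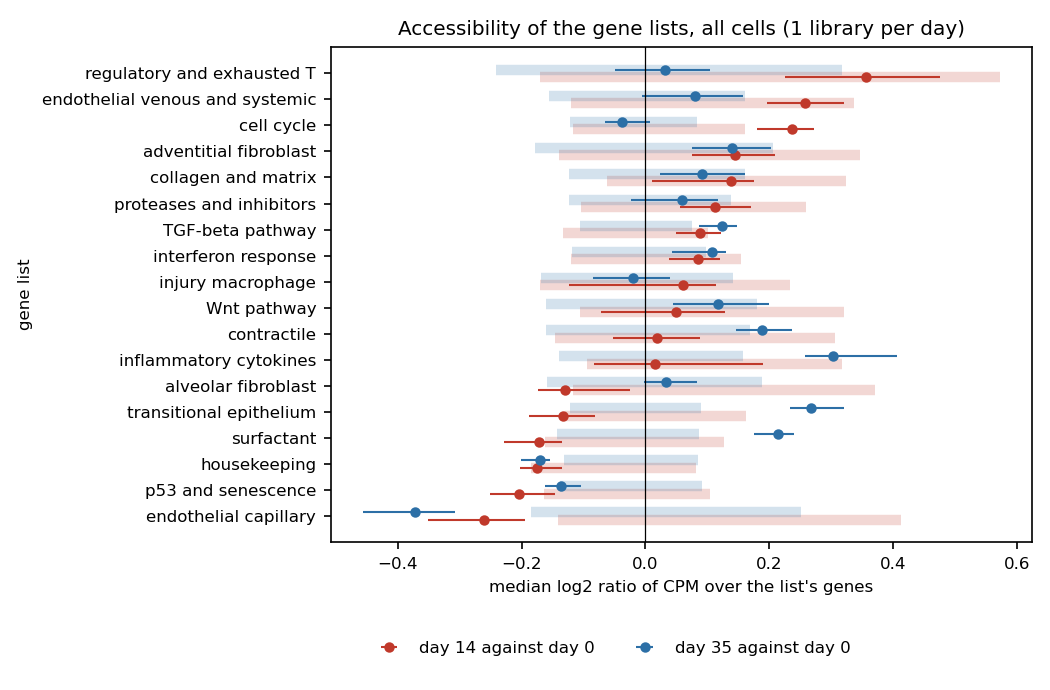
Median log2 ratio of CPM over the genes of each fixed list, in all cells, at day 14 (red) and day 35 (blue) against day 0, from 1 library per day; points are the medians, bars their 95% counting intervals, and pale bands the central 95% of 10000 random matched lists. The cell cycle list stood at 0.24 at day 14 and −0.04 at day 35.

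Of the 4 genes tied to the study's interest in anti-fibrotic fibroblast factors, Csmd1 and Cd248 had no region with a peak of every library. Csmd1 had a peak on day 0 alone, and Cd248 on days 0 and 35 but not on day 14. Pi16, a marker of adventitial fibroblasts, had 39.3, 26.0 and 38.3 CPM on days 0, 14 and 35 (ratio 0.662, 0.613 to 0.715 at day 14, and 0.975, 0.918 to 1.04 at day 35). Serpine2, a secreted protease inhibitor, had 16.7, 20.8 and 18.5 CPM, with a ratio of 1.11 (1.02 to 1.22) at day 35. In the fibroblast-like class Serpine2 had 39.2 against 26.1 CPM at day 14 (ratio 1.51, 1.18 to 1.92) and Pi16 16.9 against 26.8 (ratio 0.633, 0.454 to 0.862).

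Joint clustering of the barcodes gave 11 clusters, of which 10 could be named from the fixed markers. On days 0, 14 and 35 the macrophage and monocyte-like class held 3.27%, 20.9% and 7.38% of barcodes (exact binomial interval at day 14, 20.3% to 21.5%). The AT1-like class held 4.72%, 13.0% and 11.4%, AT2-like 15.1%, 4.67% and 17.9%, club and secretory-like 13.1%, 7.78% and 15.9%, and ciliated-like 11.7%, 3.67% and 10.6%. Endothelial-like barcodes made up 22.5%, 6.17% and 10.2%, fibroblast-like 11.7%, 8.74% and 5.84%, T-like 4.90%, 10.0% and 2.61%, B-like 7.57%, 8.75% and 3.90%, and mesothelial-like 0.559%, 0.379% and 1.93%, too few to compare. The unnamed cluster held 4.96%, 15.9% and 12.3%. These shares moved with the clustering. The AT1-like share at day 14 over day 0 was 2.76, and 1.58 at resolution 2, 1.33 with each library on its own, 1.60 with weighted components and 1.64 in barcodes with at least 6000 counts. At day 35 it was 2.42, and 1.26 with each library on its own. The AT1 marker list in all cells went the other way at day 14 (−0.23). In that clustering of single libraries, endothelial-like barcodes were 11.7%, 12.7% and 10.9%, AT2-like 14.2%, 12.5% and 18.5%, and a macrophage and monocyte-like class was named on day 14 alone (13.9%), while no fibroblast-like class was named on day 14 and no B-like or T-like class on day 35. That naming rests on thresholds set after the data were seen, and unnamed clusters of 1393 barcodes on day 0 and 1136 on day 35 also scored highest for markers of other macrophages and monocytes. With 1 library per day, a cluster mostly of 1 library can also be a trait of that library.

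**Figure D3:**
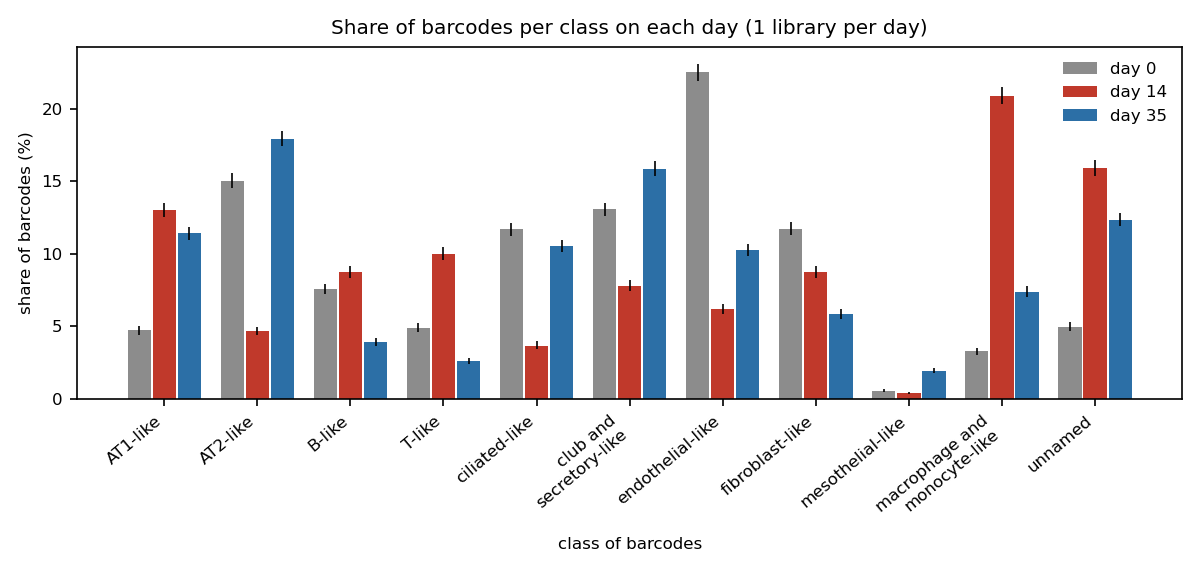
Share of barcodes (percent) in each class on days 0, 14 and 35, from 1 library per day; bars are shares and lines their exact 95% binomial intervals. The macrophage and monocyte-like class reached 20.9% on day 14 against 3.27% on day 0.

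Classes were not cleanly separated, as Sftpc on day 0 had 83.1 CPM in fibroblast-like and 88.0 in endothelial-like barcodes against 106 in all cells, so class values may hold signal of other kinds of cells. In the fibroblast-like class the collagen and matrix list had a median log2 ratio of 0.26 at day 14 (9 of 10 above 0, percentile 98.8) and 0.29 at day 35 (8 of 9, percentile 100), and the Wnt list 0.26 (5 of 5) and 0.33 (4 of 5). In every class both lists leave out genes whose library had no peak on some day. Eln, Col1a2, Lox, Col6a1, Wnt2, Wnt4, Sfrp1 and Dkk3 had a peak on day 0 but not at day 14, and Col5a2 and Wnt7b the reverse. Vcan, a large proteoglycan, had 34.7 against 20.4 CPM at day 14 (ratio 1.70, 1.29 to 2.20), Sparc 81.2 against 61.4 (ratio 1.32), Loxl1, a collagen and elastin crosslinking enzyme, 47.3 against 35.8 (ratio 1.32), Fn1 46.6 against 38.5 (ratio 1.21, 0.976 to 1.49) and Wnt5a 24.3 against 16.5 (ratio 1.47). Proteases and inhibitors had 0.24 at day 14 and 0.07 at day 35, with Mmp2 at 23.4 against 13.5 CPM at day 14 (ratio 1.73, 1.24 to 2.39). Alveolar fibroblast genes had −0.18 at day 14 (0 of 6 above 0) and −0.00 at day 35. The surfactant list, whose genes belong to AT2 cells, stood at −0.40 and 0.01 in these same barcodes.

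Named by the rule in fibroblast-like barcodes at day 14 were Calhm6 (53.4 against 16.0 CPM, ratio 3.34, 2.59 to 4.37), Gcnt4 (3.10), Sdc3 (2.85), Prss45 (2.79), Atp1a4 (2.77) and Sox30 (2.65), of which Gcnt4, Sdc3 and Sox30 rested on peaks of differing extent. In aligned regions Gfpt2, an enzyme of hexosamine synthesis, had 74.8 against 28.5 CPM (ratio 2.63, 2.15 to 3.23), and Rgs16 a ratio of 2.56. Lower were Sec14l4 (0.356), Npepps (0.374), Prdm8 (0.401), Hsp90ab1 (0.412), Il17d (0.424) and Kansl1l (0.436), the last 5 without an aligned region, and then Nr4a1 (110 against 234 CPM) and, in aligned regions, Sftpc (0.308, against 0.650 over all its regions, 54.1 against 83.1 CPM). At day 35 the rule named Zfp423 (49.6 against 11.4 CPM, ratio 4.34, 3.24 to 5.84), Nlrc3 (35.6 against 13.5, ratio 2.63, 1.96 to 3.52), Sdc3 (27.1 against 11.1, ratio 2.45), Ttc5 (2.39), Dennd2a (2.22, but 1.03 in aligned regions) and Ube2ql1 (2.21) above day 0, of which Zfp423, Sdc3 and Ube2ql1 had no aligned region. In aligned regions Steap4 (30.1 against 13.7, ratio 2.20, 1.63 to 2.98), Gfpt2 (56.5 against 28.5, ratio 1.98) and Il11, a cytokine that drives fibroblast activation (35.9 against 18.7, ratio 1.92, 1.47 to 2.49), also stood above. Kansl1l (0.491, no aligned region), Cd37 with Slc6a16, which share their regions (interval 0.325 to 0.749), Cd52 (0.502), Kcnab1 (0.506) and Armcx2 (0.506) stood below. Against day 14, day 35 was highest in Zfp423 (3.13) and lowest in Cd37 with Slc6a16 (0.299), and Hmga2 (0.453) and H3c8 (0.467) were among the lower genes in aligned regions.

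Endothelial-like barcodes of the joint clustering had higher values at their own markers after injury. The class compares different groups of barcodes in part, since at resolution 2 it split into a cluster of 2851, 95 and 361 barcodes and another of 198, 964 and 1393 on days 0, 14 and 35. Their endothelial marker list stood at 0.25 at day 14 and 0.34 at day 35 (8 of 8 above 0 each), and the venous list at 0.43 (7 of 7) and 0.17. Selp, the P-selectin that lets leukocytes roll, had 14.5, 47.0 and 36.2 CPM (ratio 3.24 at day 14), from a region that is not aligned. Ntrk2, a neurotrophin receptor, had 23.4, 41.0 and 57.5 (ratio 2.46, 2.09 to 2.89 at day 35). Serpina3n, an acute-phase protease inhibitor, had 47.4 against 14.1 CPM at day 14 (ratio 3.37, 2.60 to 4.31) and Hunk 28.0 against 5.98 (ratio 4.68, 3.24 to 6.64). Lower were Kcnma1 (0.207) and Mlc1 (0.284) at day 14, and Kcnma1 (0.401) and Angpt1 (0.416) at day 35.

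In macrophage and monocyte-like barcodes Pdpn had 8.26, 24.4 and 31.1 CPM (ratio 2.95, 1.74 to 5.85 at day 14, and 3.76, 2.21 to 7.53 at day 35), and Ccl2 13.5, 30.8 and 31.9. The collagen and matrix list stood at 0.36 and 0.40 there, with Fn1 at 38.4 against 20.2 CPM at day 14 (ratio 1.90, 1.32 to 2.81), and the injury macrophage list at 0.17 and 0.28. Gja1 (3.26) and Celf3 (3.26) were also higher at day 35, and Cxcl1 was lower at day 14 (10.5 against 21.4 CPM, ratio 0.492, 0.325 to 0.749).

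Club and secretory-like barcodes had Retnla at 13.8, 38.6 and 29.8 CPM (ratio 2.79, 2.12 to 3.73 at day 14) and Chil4, which encodes a chitinase-like protein, at a ratio of 1.99 (1.75 to 2.28) at day 35. AT2-like barcodes had Fcer2a at 3.31 (2.21 to 4.92) at day 14, and Corin (31.2 against 10.1 CPM, ratio 3.08, 2.41 to 3.98) at day 35, with Gimap6 (0.376) and Enpp2 (0.375) lower. AT1-like barcodes had Fyb (96.3 against 27.8 CPM, ratio 3.46, 2.69 to 4.59) and Dhrs9 (4.09, 2.35 to 7.70) at day 14, and Lyz2 (3.11), Ntf3 (2.73) and Aoah (2.73) at day 35. Fyb, Lyz2 and Ntf3 had their highest class values in AT2-like barcodes on those days. Ciliated-like barcodes had Serpinb1b (2.51) and the interferon-induced Iigp1 (2.43) at day 14. Among lymphocytes at day 14, B-like barcodes had Plk1, a mitotic kinase, at 31.7 against 11.8 CPM (ratio 2.69, 1.89 to 3.90), and T-like barcodes had Btn2a2 at 2.31. T-like barcodes had the histone gene H3c8 at 0.387 (0.265 to 0.539) at day 35 against day 14.

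Far more shared regions stood above day 0 at day 14 than at day 35. At least 2-fold higher than day 0 were 469 regions at day 14 and 59 at day 35, and 70 and 43 were at least 2-fold lower, and between day 35 and day 14 the counts were 26 higher and 421 lower. In aligned regions the day 14 counts were 369 and 45, those of day 35 were 29 and 35, and those between both days 5 and 357. With the median of ratios as the scale, 314 were higher and 105 lower at day 14, 50 higher and 59 lower at day 35, and 35 higher and 329 lower at day 35 against day 14. All these counts leave out regions without a peak on some day. Of those, 8981 lacked a peak on day 14 alone, 1438 on day 35 alone and 4063 on day 0 alone. Regions low enough at day 14 to have no peak there are thus missing. The balance of higher and lower regions holds for shared regions only. On mm10, the highest ratios at day 14 were on chromosome 4 from 135405914 to 135406929 (5.87, nearest gene Rcan3), on chromosome 11 from 50396338 to 50397547 (5.23, within Rufy1) and on chromosome 3 from 89796011 to 89796925 (4.76, nearest gene Ube2q1), all with narrower peaks on day 0. The highest aligned region that lay in a gene was on chromosome 15 from 6564723 to 6565574, within Fyb (17.5 against 5.16 CPM, ratio 3.39), an adaptor protein of T cells and myeloid cells. The lowest were on chromosome 17 from 45572337 to 45573714 within Hsp90ab1 (0.207) and on chromosome 5 from 67788773 to 67789806 within Atp8a1 (0.336), with differing peaks, and on chromosome 15 from 11801926 to 11802788 (11.3 against 37.6 CPM, ratio 0.300, aligned), 37108 bp from Npr3. Whether a region lay in an exon or an intron was not analysed here.

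The rule named further regions in the other comparisons. At day 35 against day 0, higher regions lay within Ctnna1 on chromosome 18 (35177365 to 35178153), within Rufy1 as above and near Car8 on chromosome 4 (8136907 to 8137795). Lower regions lay near Pls3 on chromosome X (75728208 to 75729049), within Sytl3 on chromosome 17 (6660851 to 6661749) and within Hmbox1 on chromosome 14 (64935877 to 64936890). At day 35 against day 14, the regions within Hsp90ab1 and Atp8a1 above were higher, as was one within Nr3c1, the glucocorticoid receptor gene, on chromosome 18 (39488374 to 39490920). A region within Treml2 on chromosome 17 (48300014 to 48301201), one on chromosome 4 (122049492 to 122050318) and the one near Ube2q1 were lower. The regions within Rufy1, Hsp90ab1, Atp8a1 and Treml2 and near Ube2q1 had peaks of differing extent. Whether the peaks align is not given here for the other regions of this paragraph, so peak width stays open for all of them.

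Peak lists of the days overlapped less where day 14 was the other list. Of day 0 peaks, 68.4% (exact interval 68.0% to 68.8%) overlapped a day 14 peak and 83.4% a day 35 peak, and of day 14 peaks 79.6% and 85.6% overlapped peaks of days 0 and 35. Of day 35 peaks, 76.0% overlapped day 0 and 67.1% day 14. With the lists held to equal length the day 0 and day 35 lists overlapped each other by 83.0% and 82.7%, and each other pair by 73.4% to 73.8%.

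Transcription factor motifs were compared as the share of a library's counts in peaks that the deposited table ties to each motif. At day 14, motifs of PU.1 (0.44, 3 of 3 above 0, percentile 99.1), a factor of myeloid and B cells, of MAF (0.33, 9 of 9, percentile 99.9), ETS (0.15, 17 of 18, percentile 99.8) and AP-1 (0.16, 30 of 40, percentile 100; 0.17 in regions tied to the motif on all days) had higher medians of log2 ratio than at day 0. Those of NRF2 (0.39), TCF and LEF (0.23), CEBP (0.14) and p53 (0.27; 0.50 in those regions) were also above 0, and SRF and MEF2 (−0.32, percentile 1.45), steroid receptors (−0.32; −0.10 in those regions) and EBF and PAX (−0.15; 0.19 in those regions) below. Motifs of PU.1, ETS, NRF2 and SRF and MEF2 had no value in those regions. At day 35, AP-1 had 0.26 (36 of 40, percentile 100; −0.0166 in those regions), p53 0.59 (percentile 99.8; 0.16 in those regions), NRF2 0.48, TCF and LEF 0.29 (−0.0312 in those regions) and mesenchymal bHLH factors 0.19 (percentile 97.7; 0.00349 in those regions), while steroid receptors had −0.26 and EBF and PAX −0.20. Against day 14, day 35 was lower in ETS (−0.22, percentile 0), MAF (−0.28) and NF-kB (−0.23), and higher in nuclear receptors (0.18, percentile 99.1; −0.14 in those regions) and SRF and MEF2 (0.21). Peaks tied to a motif differ between libraries, and in regions tied to it on all days 0.00%, 0.319% and 0.639% of motifs were at least 1.5-fold apart, against 4.73%, 4.87% and 5.82% over all of its peaks.

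The medians of the remaining motif lists, at day 14 against day 0, day 35 against day 0 and day 35 against day 14, were TEAD (−0.07, 0.10, 0.07), SMAD (−0.04, 0.04, 0.16), RUNX (0.08, 0.02, 0.02), IRF (0.01, −0.04, −0.00), STAT (0.04, 0.09, 0.05), NFI (0.05, 0.19, 0.13), FOX (−0.03, 0.02, 0.04), NKX2 (0.01, 0.10, 0.09), GATA (−0.01, 0.07, 0.13), KLF and SP (0.09, −0.02, −0.04), CTCF (−0.07, −0.10, −0.03), RFX (0.01, −0.01, −0.04), SOX (−0.04, −0.00, 0.07), T-box (−0.00, 0.13, 0.11), ROR (−0.12, −0.14, −0.05), HIF (−0.04, −0.05, 0.00) and POU2 (−0.07, −0.01, 0.13). NF-kB stood at 0.12 and 0.01 against day 0. In regions tied to the motif on all days, TEAD had −0.11, SMAD −0.19, NKX2 −0.19, GATA −0.18 and SOX −0.20 at day 35 against day 14. Single motifs named by the rule rested on 1 to 35 recovered peaks, or on peaks that could not be recovered, and many had a value near 0 or of the other sign in regions tied to the motif on all days. The highest at day 14 were ZNF274 (1.01; −0.16 in those regions), CEBPB (0.96), SOX12 (0.89), RELB (0.81), GFI1 (0.81), Atoh1 (0.80), ZNF449 (0.63) and a BACH2 variant (0.62), and the lowest ZBTB7B and ZBTB7C, which share peaks (−3.36; −0.13 in those regions), ZFP57 (−2.06), EGR4 (−1.34), GLIS1 (−1.11), HOXA9 (−1.08; 0.18), PAX5 (−1.06; 0.06) and DUX4 (−0.94; 0.06). At day 35 they were ZNF274 (1.24; −0.08 in those regions), TP63, ZNF136 (−0.03 there), SNAI2, GFI1, SOX12 (−0.62 there), DUX4 (−0.21 there) and ZNF317 (0.85), and EGR4 (−1.67), ZFP57, PAX5, GLIS3, NRL (0.12 there), HES5, MYBL2 and GCM1 (−0.85). Against day 14, day 35 had ZBTB7B and ZBTB7C (3.08), DUX4, SNAI2, MYCN, HOXA9, MYOD1 and NFYA (1.06) highest, of which NFYA had no value in those regions and the others were below 0 there (−0.06, −0.27, −0.20, −0.12, −0.28 and −0.25), and NRL (−1.32), MYBL2, a CREB3L4 variant, CENPB, RELB, OVOL2, MAFF and HOXD10 (−0.61) lowest.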

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

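These results stood out because the day 14 and day 35 values lay on opposite sides of day 0, and the differences between days were not tested, with 1 library each. All tests in this part were chosen after the results were seen. The AT1 markers had median log2 ratios of −0.23 at day 14 and 0.26 at day 35, the B cell markers 0.51 and −0.29, the surfactant list −0.17 and 0.21, and the transitional epithelium list −0.13 and 0.27.

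For the surfactant and transitional epithelium lists, aligned regions gave −0.17 and 0.22 for surfactant and −0.13 and 0.27 for transitional epithelium. Peaks of clearly different extent thus do not account for the opposite signs. Aligned regions were 30534 of the 32979 shared regions, and width still went with ratio in them (Spearman 0.20 at day 14 and 0.24 at day 35 against day 0). Smaller differences of width stay open. Barcodes with at least 6000 counts gave 0.00295 and 0.20 for surfactant and −0.0647 and 0.25 for transitional epithelium. An effect of few counts stays open, since these barcodes were 38.1%, 11.8% and 77.9% of days 0, 14 and 35, and the AT2-like share of day 14 was 10.9% among them against 4.67%. With class shares held at day 0 the medians were −0.0526 and 0.0726 for surfactant and −0.18 and 0.14 for transitional epithelium, and since the classes were formed partly from these genes, a different mix of cells stays open. A biological difference between the days stays open as untested.

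The rule named 36 entries in all cells over the 3 comparisons, with a gene counted in each comparison that named it. Ptafr, Kansl1l, Zfp423, Plxnb1, Spry1, Prdm8 and Treml2 were thus counted repeatedly, and Ctla2a and Tpbpa share their regions. Of the entries, 35 had the same direction in every class measured. Of these 35 entries, 18 had no aligned region and thus no value to test, so peaks of different width stay open for them. The other 17 kept a 1.5-fold ratio in aligned regions, which argues against peaks of clearly different extent for these. Of all entries past 1.5-fold with an aligned region, 56 of 1203 lost it there, and smaller differences of width stay open. The class with the highest value of each of these 17 entries differed in share in the same direction in 17 of 17 cases in the joint clustering. With each library clustered on its own this held for 9 of the 10 that had that class on both days. In the joint clustering 81.6% of all entries past 1.5-fold in aligned regions did so too. Counts of other cells in each barcode may thus spread the signal, but this stays open. With class shares held at day 0 the median size of the log2 ratio of the 17 entries was 0.88 against 1.18. A different mix of cells therefore stays open, as does a biological difference between days, untested.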

How the results depend on the processing

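No paired analysis was possible because each day was 1 library. Results that kept their value, moved or reversed were 315, 29 and 0 for gene accessibility, 427, 112 and 4 for gene lists, 461, 58 and 3 for motif lists and 66, 50 and 3 for cell shares. The numbers for cell shares leave out every class that a setting did not name. A class lost in this way counts as neither moved nor reversed, so these numbers understate how far the shares depend on the clustering. Of the motif lists, 47 of those that moved, all 3 that reversed and only 7 of those that kept their value come from regions tied to a motif on all days. Some settings altered no value, which gave 39 kept results of gene accessibility each from the minimum of 3000 counts and from no minimum per gene, 93 of motif lists from the former, and 18 of cell shares each from the former and from every deposited barcode. The share of genes at least 1.5-fold apart moved only at day 35 against day 14, to 7.28% with all peaks as the scale. Thinning to 1000 counts gave 1 cluster and no share, and the minimums of 1000 and 3000 counts left out nothing. For all values below the cause was not tested. Peak overlap with 50% both ways was 82.9% (day 0 by day 35) and 85.2% (day 14 by day 35). With lists of equal length, overlap was 73.5% and 83.0% of day 0 peaks by days 14 and 35, 73.4% and 73.8% of day 14 peaks by days 0 and 35, and 82.7% and 73.7% of day 35 peaks by days 0 and 14.

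The AT2-like share at day 14 over day 0 (0.310) was 0.179 at resolution 2, 0.884 with each library on its own, 1.02 with weighted components and 0.996 in barcodes with at least 6000 counts, and the last 2 settings were chosen after seeing the data. At day 35 the AT2-like ratio (1.19) was 2.19 weighted and 1.83 from 6000 counts. The T-like ratio (2.05) was 1.78 at resolution 2, 1.77 without high doublet scores and 1.49 with libraries on their own, and the ciliated-like ratio at day 35 (0.903) was 1.03 at resolution 2. No T-like class was named with weighted components or in barcodes with at least 6000 counts, and no B-like class with weighted components. At resolution 0.5 only B-like and endothelial-like classes were named. At day 14 the ciliated-like ratio (0.314) was 0.631 with libraries on their own and 0.191 from 6000 counts. From 6000 counts the fibroblast-like ratio was 0.412 at day 14 (0.746) and 0.326 at day 35 (0.498). The endothelial-like ratio at day 14 (0.274) was 0.0631 and 0.377 at resolutions 0.5 and 2, 0.358 without high doublet scores, 1.08 with libraries on their own and 0.293 weighted, and at day 35 (0.454) it was 0.359, 0.576, 0.511, 0.928 and 0.556, and 0.508 from 6000 counts. The class of resolution 0.5 was a mixed cluster of 72.8% of day 0 barcodes, led by Btg4 and Hoatz of the ciliated-like class besides Erg, so its ratios are not of endothelial cells alone. The macrophage and monocyte-like ratio at day 14 (6.40) was 8.82 weighted.

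Regions at least 2-fold lower at day 14 were 45 when aligned. Those higher at day 35 than at day 0 were 32 with matched widths and 29 when aligned, and than at day 14 they were 5 and 5. With class shares held at day 0, medians at day 14 were −0.0101 for endothelial capillary, 0.0539 for lymphatic, −0.0526 for surfactant and 0.35 for PU.1 motifs, at day 35 −0.13 for capillary, 0.0726 for surfactant and 0.14 for transitional epithelium, and against day 14 −0.0541 for adventitial fibroblast and 0.17 for surfactant. At gene ends, capillary genes had −0.50 at day 14, and at day 35 the TGF-beta pathway had −0.000773 and surfactant 0.16. In barcodes with at least 6000 counts, day 14 medians were 0.16 for cell cycle, −0.41 for capillary and 0.00295 for surfactant, and surfactant against day 14 was 0.20. In regions tied to a motif on all days, chosen after seeing the data, 0.00%, 0.319% and 0.639% of the motifs with a value there were 1.5-fold apart. In these regions MAF had 0.28 at day 14, AP-1 −0.0166, TCF and LEF −0.0312 and p53 0.16 at day 35, and nuclear receptors −0.14 at day 35 against day 14.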

Other observations

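Cell cycle genes were higher at day 14 than at day 0 in 10 of 10 classes, from a median log2 ratio of 0.07 in ciliated-like to 0.35 in club and secretory-like barcodes. The tests of this pattern were chosen after the results were seen. With class shares held at day 0 the all-cell median was 0.21, so the shares of these classes do not account for it. As the classes were not cleanly separated, a different mix of cells within them stays open. In aligned regions the median was 0.24, so peaks of clearly different extent do not account for it. Width still went with ratio there (Spearman 0.20), so smaller differences of width stay open. Since even the lowest class median was 0.0682, counts of dividing cells of 1 kind in the barcodes of every class could give the same pattern as division in many kinds of cells, and this stays open, as does a biological difference between the days, untested.

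Peak width and ratio went together across the shared regions that were not aligned, with Spearman correlations of 0.46 at day 14 against day 0, 0.53 at day 35 against day 0 and 0.61 at day 35 against day 14, and 0.20, 0.24 and 0.24 in aligned regions. The Arid3a motif took 27.3%, 28.6% and 28.7% of all counts on days 0, 14 and 35.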
